A study of Mus musculus with 12 samples.

How the data were processed

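Poly(A) RNA of E14 mouse embryonic stem cells and of their differentiated progeny was sequenced in 12 libraries, 3 in each of 4 groups: undifferentiated mESC, and cells sorted as T+, SOX17+/T+ or SOX17+ by reporter expression. Per the labels, 500 ng of total RNA entered a stranded library preparation for each sample, and the libraries were sequenced with 100 bp paired-end reads. The labels state a minimum number of fragments per library, and the number reached by each library is not given in the sources used here. The submitters' processing notes name cutadapt, STAR and StringTie, without versions, and the builds mm10 and GRCm38. The annotation release and any filters are not given in the sources used here. The authors deposited 1 table of TPM values, which are scaled to the same total in every library, with 1 column per library. Counts were not used here, so no count-based test was run, and the depth behind a single value is unknown. The table holds 54480 rows with 282 empty cells. Empty cells were set to 0, and the rows of 11 genes that were split over several rows were summed per gene identifier, which left 54446 genes. Gene coordinates are those of the table, in GRCm38, counted from 1.

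Values were transformed as log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 of the 12 libraries were kept, which left 16097 genes. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust set), so that all comparisons share 1 estimate of the spread with 8 residual degrees of freedom. The 2-sided moderated test of limma was adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The 6 pairwise comparisons of the groups were made, together with the difference of the SOX17+/T+ mean from the mean of the SOX17+ and T+ means on the log2 scale. A gene lay beyond both single-positive groups when it was called in the same direction against each. The position of each SOX17+/T+ library was its projection on the line from the T+ mean (0) to the SOX17+ mean (1), over genes called between these groups with at least a 2-fold difference. No test was made on it.

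The comparisons, tests, gene lists, rule for named genes and all but 1 of the alternative settings were chosen before the data were examined. The 31 lists of textbook markers are naive pluripotency, general pluripotency, primed epiblast, primitive streak, definitive endoderm, anterior gut endoderm, mid and hindgut endoderm, extraembryonic endoderm, endothelium, primitive blood, paraxial mesoderm, lateral and cardiac mesoderm, axial progenitors, node and notochord, neural, primordial germ cells, feeder fibroblasts, two-cell-like cells, epithelial, mesenchymal, WNT targets, NODAL pathway, FGF pathway, BMP pathway, retinoic acid pathway, HOX paralogs 1 to 4, HOX paralogs 5 to 13, cell cycle, glycolysis, dissociation stress and mitochondrially encoded. They hold 317 different genes, all found in the table, and some genes belong to more than 1 list. Each list was tested in each of the 7 comparisons with camera from limma, with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated from the data. Of the 217 tests, 116 were called with the preset and 11 with the estimated correlation. The p with the estimated correlation is given beside each list call. The numbers of called members are counted over all tested genes and adjusted over the list alone.

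Genes are named by a fixed rule. T and Sox17 are named with the values of every library. In each pairwise comparison, the 8 largest rises and the 8 largest falls were taken among called genes whose 3 libraries in 1 group all lay above those of the other and whose mean was at least 10 TPM in the higher group, leaving out symbols of predicted genes, RIKEN clones and bare identifiers. For the midpoint and the genes beyond both groups, the 6 largest each way were taken by the same rule without the condition on single libraries. From each list, up to 4 called members with the largest absolute change can be named, and for lists of other cell types also the 2 members with the highest mean TPM. Values of list members in other comparisons are given as TPM. Members of 2 further lists, of fibroblast and erythroid genes, are named from those lists, which were written after the first results and before the values of their genes were seen. H1fx was chosen after its values were seen.

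Within a group, 10 to 14 genes were listed at 0 in 1 library and at 5 TPM or more in another, among them H1fx and Defa30. An exact 0 can therefore be a failed estimate, so no fold change is given against a group listed at 0 throughout. Groups carry the same replicate numbers. After the group means were removed, libraries of T+ and SOX17+/T+ with the same number correlated at r = 0.204, 0.149 and 0.242 across genes, each higher than any other pairing between the groups, and the numbers were taken to pair these groups before the fits were compared. The main fit nevertheless had no block, as set beforehand, so values for SOX17+/T+ against T+ were unpaired unless the block is named. No other pair of groups had all same-number correlations above 0.1. Alternatives were a pseudocount of 0.1, no filter or a filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, no robust moderation, library weights, the replicate number as a block, a fit on the compared groups alone, an added 2-fold threshold, and leaving out each library in turn. The position was also computed over all called genes, and over genes chosen from replicates 1 and 2 with the ends of the axis from replicate 3.

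The procedure was tested on simulated data with the means and spreads of these genes. Changed genes were drawn from those with a mean log2(TPM + 1) above 2. Of 100 genes changed by 0.5 on the log2 scale, 81 to 87% were called in the 7 comparisons, and of 100 genes changed by 1, 98 to 100%. There were 6 to 13 false calls among 14796 to 14818 genes tested. The changed list was called in every comparison, and none of 30 unchanged lists was. Noise was drawn independently for each gene, so these simulations do not show how often lists of genes that vary together are called falsely. Of the genes set beyond both groups, 78% and 99% were found at these sizes, with 0 false ones, and simulated positions of 0.2 and 0.7 were estimated at 0.202 and 0.696. For the calls, all groups were given the same means apart from the changed genes. The 0 false ones therefore do not cover genes that differ between the single-positive groups. Mitochondrially encoded genes were kept in the main values. No library and no value column was left out.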

Results

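E14 mouse embryonic stem cells and 3 cell populations differentiated from them were profiled by RNA sequencing, with 3 libraries in each of 4 groups. Undifferentiated cells (mESC) had been grown with serum and LIF, a cytokine that maintains self-renewal, on irradiated embryonic fibroblasts that serve as feeders. The other groups were sorted by reporters for T (Brachyury), a T-box factor of the primitive streak and nascent mesoderm, and for SOX17, an HMG-box factor of endoderm. They are called T+, SOX17+/T+ (double-positive) and SOX17+, and the comparisons between them address how definitive endoderm emerges beside T-expressing cells. Levels are mean TPM as deposited by the authors ± SD over the n = 3 libraries of a group. Fold changes are differences of log2(TPM + 1) ± the standard error of the limma fit, a scale that understates changes in genes near or below 1 TPM. With a pseudocount of 0.1, the fold changes of genes near 0 in 1 group, such as Msgn1, Shh and Nkx2-1, were over 1.5 times as large and stayed called. A gene was called at a Benjamini-Hochberg adjusted limma p under 0.05, and only called genes are described as rising or falling. The labels do not state that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries. The sequencing depth behind each TPM value is not given in the table, so the precision of single low values is unknown. Gene lists were tested with camera, with a preset correlation and then with one estimated from the data. Counts of list members adjusted over the list alone are given where they differ from the counts over all tested genes.

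The reporter genes followed the sort, so their differences between the groups, also as members of gene lists, can follow from the gates. T (ENSMUSG00000062327.10, chromosome 17, 8434423 to 8442496 in GRCm38) was listed at 0.65, 0.618 and 0.673 TPM in the mESC libraries, 132, 92.1 and 158 TPM in T+, 40.4, 31.7 and 61.5 TPM in double-positive and 2.27, 1.86 and 2.84 TPM in SOX17+ replicates 1, 2 and 3. Sox17 (ENSMUSG00000025902.13, chromosome 1, 4490931 to 4497354) was listed at 0.798, 0.484 and 0.632 TPM in mESC, 7.96, 9.99 and 12.9 TPM in T+, 148, 146 and 123 TPM in double-positive and 244, 211 and 235 TPM in SOX17+. The double-positive libraries therefore held both transcripts, which does not show both in the same cell, T at a mean of 44.5 ± 15.3 TPM against 127 ± 33.1 TPM in T+. Sox17 stood at 139 ± 13.8 TPM against 229.9 ± 16.7 TPM in SOX17+. T in double-positive cells was lower than in T+ (log2 fold change -1.52 ± 0.24, adjusted p = 8.0e-04). Sox17 in double-positive cells was lower than in SOX17+ cells, which stood 0.73 ± 0.14 above them (adjusted p = 0.0016). Both transcripts were higher in every sorted population than in mESC, including Sox17 in T+ (2.77 ± 0.14, adjusted p = 1.7e-09) and T in SOX17+ (1.0 ± 0.24, adjusted p = 0.0023). Across all tested genes, libraries of a group correlated at Pearson's r = 0.995 to 0.997 (across genes, which are not independent replicates). T+ correlated with double-positive at 0.983 to 0.987, double-positive with SOX17+ at 0.981 to 0.984, T+ with SOX17+ at 0.954 to 0.958, and mESC with the sorted groups at 0.822 to 0.835.

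**Figure D1:**
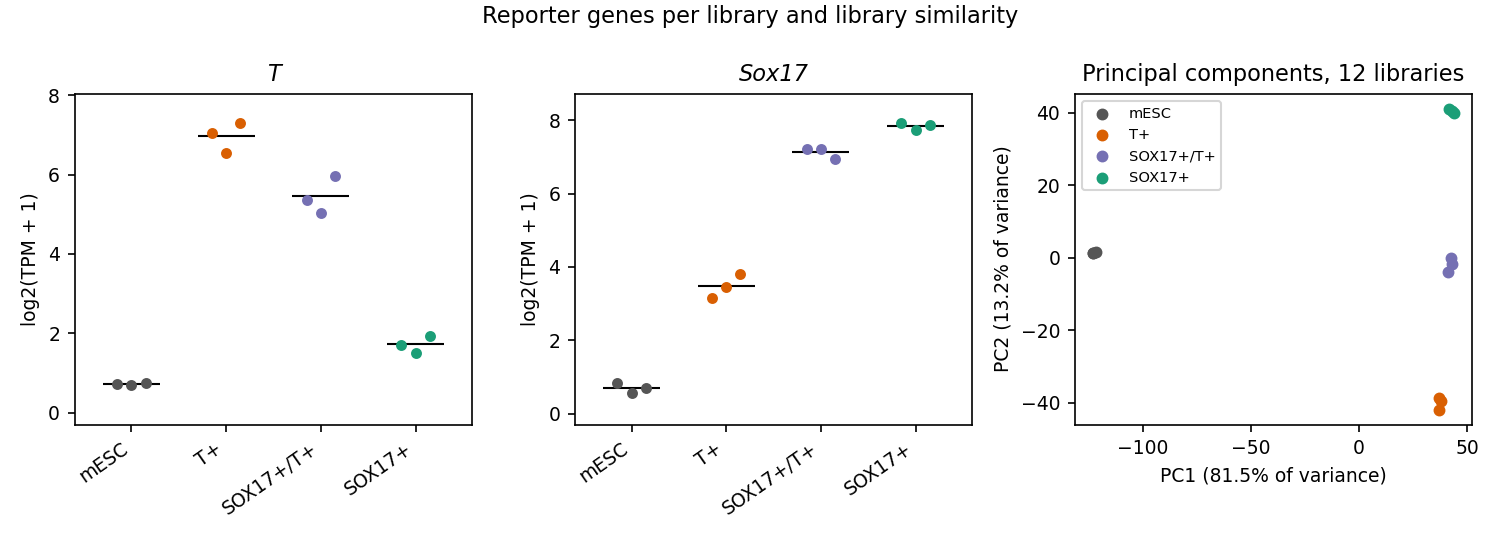
T and Sox17 as log2(TPM + 1) in each of the 12 libraries (points, by group, with short lines for group means), beside the first 2 principal components of log2(TPM + 1) over all tested genes with 1 point per library. T was highest in the T+ libraries and Sox17 in the SOX17+ libraries, PC1 (81.5% of the variance) set mESC apart, and along PC2 (13.2%) the double-positive libraries lay between T+ and SOX17+.

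SOX17+ cells were compared with mESC to describe what the endoderm reporter population had gained and lost relative to undifferentiated cells. All 14 measured definitive endoderm genes rose, with a median log2 fold change of 4.65 (camera, adjusted p = 8.9e-07, but 0.13 with estimated correlation). Beside Sox17 itself (7.14 ± 0.14), the largest rises in this list were in the simple-epithelium keratins Krt18 (5.68 ± 0.08) and Krt8 (5.47 ± 0.09) and in the pioneer factor Foxa2 (5.44 ± 0.22). Of the epithelial genes, 10 of its 12 measured members rose, 1 fell and 1 did not pass the test (camera, adjusted p = 2.7e-04, but 0.25 with estimated correlation), with the tight junction genes Cldn7 (4.85 ± 0.07) and Cldn6 (4.04 ± 0.09) among them. The naive pluripotency list fell in all 14 genes (camera, adjusted p = 1.1e-05, but 0.098 with estimated correlation). Zfp42 (Rex1) dropped from 515 ± 17.8 to 0.847 ± 0.341 TPM, Klf2 from 338 ± 21 to 0.313 ± 0.0697 TPM and the nuclear receptor Esrrb from 319.8 ± 16.8 to 0.726 ± 0.289 TPM. Of the general pluripotency genes, 10 of its 11 measured members fell and 1 rose (camera, adjusted p = 8.3e-04, but 0.18 with estimated correlation), and Dppa5a fell from 2119 ± 24.4 to 3.17 ± 0.202 TPM.

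Among single genes outside these lists, the largest rises in SOX17+ cells were the transmembrane protease Tmprss2 (7.74 ± 0.08), the bHLH factor Hand1 (7.45 ± 0.07), Clic6 (7.37 ± 0.10), the NODAL co-receptor Cfc1 (7.16 ± 0.07), the carboxypeptidase Cpm (6.9 ± 0.07), the secreted WNT antagonist Dkk1 (6.44 ± 0.13) and the acylglycerol transferase Mogat2 (6.38 ± 0.07). Tmprss2 and Clic6 reached 228 ± 6.0 and 234 ± 8.77 TPM. All 9 genes of the BMP pathway list rose (camera, adjusted p = 1.6e-05, but 0.13 with estimated correlation), led by the homeobox genes Msx1 (6.33 ± 0.08) and Msx2 (5.67 ± 0.06). Of the WNT targets, 8 of its 10 measured members rose, 1 fell and 1 did not pass the test (camera, adjusted p = 9.0e-04, but 0.20 with estimated correlation). Among them were Nkd1 (4.97 ± 0.07), Rnf43 (4.0 ± 0.08) and Lgr5 (2.65 ± 0.16). Markers of blood and vessel cells rose beside the endoderm genes. All 7 measured primitive blood genes were higher (camera, adjusted p = 8.1e-04, but 0.31 with estimated correlation), among them Gata1 (2.58 ± 0.17) and Itga2b (2.68 ± 0.11). The embryonic globin Hbb-bh1, listed at 0 in every mESC library, stood at 51.9, 75.8 and 141 TPM in the SOX17+ libraries. Of the endothelial genes, 9 of its 11 measured members rose, 1 fell and 1 did not pass the test (camera, adjusted p = 6.1e-04, but 0.24 with estimated correlation). Examples were Kdr (3.49 ± 0.09), Cdh5 (3.68 ± 0.10) and Tie1 (3.55 ± 0.12). The lateral and cardiac mesoderm list rose in 8 of 9 genes and fell in 1 (camera, adjusted p = 6.3e-04, but 0.13 with estimated correlation). The list included Isl1 (4.17 ± 0.11) and Tbx20 (3.65 ± 0.16). The anterior gut list did not pass as a set (camera, adjusted p = 0.12), although Nkx2-1 (3.93 ± 0.10) rose and Lefty1 (-6.81 ± 0.19) fell. The extraembryonic endoderm list did not pass either (camera, adjusted p = 0.061), with 7 of 12 genes higher and 3 lower. In it Ttr (6.16 ± 0.15) and Hnf4a (3.73 ± 0.08) rose and Lrp2 (-3.38 ± 0.10) fell.

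The glycolysis list was higher in SOX17+ cells (11 of its 14 measured members rose, 2 fell and 1 did not pass the test; camera, adjusted p = 0.0014, but 0.43 with estimated correlation), with the glucose transporters Slc2a3 (2.9 ± 0.15) and Slc2a1 (2.61 ± 0.12), against a median of -0.18 over all genes. The cell cycle list was lower in 14 of 15 genes and 1 did not pass the test (camera, adjusted p = 8.1e-04, but 0.27 with estimated correlation). These included Ccnb1 (-1.82 ± 0.06) and Aurka (-1.64 ± 0.06). Immediate-early and heat-shock genes of the dissociation stress list fell in 9 of 10 genes and 1 rose (camera, adjusted p = 0.024, but 0.25 with estimated correlation). Among them were Fosb (-5.1 ± 0.13) and Fos (-3.82 ± 0.12). The mESC had been grown on fibroblast feeders, and fibroblast genes fell with the pluripotency genes. Of the feeder fibroblast list, 13 of its 14 measured members fell and 1 rose (camera, adjusted p = 2.8e-04, but 0.28 with estimated correlation). Its 2 most abundant members, Acta2 and Tagln, stood at 1006 ± 127 and 722 ± 77.7 TPM in mESC against 7.14 ± 0.498 and 7.54 ± 1.98 TPM in SOX17+. Spp1 (-8.52 ± 0.14), Tnc (-8.45 ± 0.09) and S100a6 (-8.29 ± 0.15) were among the largest falls. S100a4 went from 265 ± 19.8 TPM in mESC to being listed at 0 in all SOX17+ libraries. By limma, 13746 of 16097 tested genes were called, 5704 higher and 8042 lower. Of these, 5068 changed at least 2-fold (1777 higher, 3291 lower). As deposited, the median log2 fold change over all genes was -0.18, against -0.05 with median-of-ratios scaling and 0.05 with quantile normalization. The share of called genes that were higher was 41.5% as deposited, 47.5% and 52.4%, so the direction of small changes against mESC depended on the scaling. Mitochondrially encoded transcripts made up 5.98 ± 0.241% of the TPM in SOX17+ and 4.16 ± 0.167% in mESC.

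T+ cells were compared with mESC to describe the population with the streak and mesoderm reporter. The paraxial mesoderm list rose in 10 of 11 measured genes (camera, adjusted p = 4.8e-05, and 0.042 with estimated correlation). The bHLH factors Mesp1 and Msgn1 reached 78.2 ± 14.9 and 51.8 ± 11.1 TPM, and the T-box gene Tbx6 rose from 0.177 ± 0.0393 to 25.2 ± 5.33 TPM (4.46 ± 0.16). Of the primitive streak list, 10 of its 11 measured members rose, 0 fell and 1 did not pass the test (camera, adjusted p = 6.6e-05, but 0.29 with estimated correlation), led by T (6.25 ± 0.24), Fgf8 (4.52 ± 0.22), Evx1 (4.21 ± 0.12) and Wnt3 (3.33 ± 0.09). All 8 node and notochord genes rose (camera, adjusted p = 5.9e-04, but 0.37 with estimated correlation). Examples were Shh (4.26 ± 0.34), Foxa2 (3.76 ± 0.22) and Nog (3.61 ± 0.16). The lateral and cardiac mesoderm list rose in 7 of 9 genes, with 1 lower and 1 not called (camera, adjusted p = 5.2e-04, but 0.10 with estimated correlation). Hand1 reached 683 ± 44.5 TPM (8.81 ± 0.07), and Foxf1 (4.78 ± 0.09) and Hand2 (4.47 ± 0.11) rose with it. HOX genes of paralog groups 1 to 4 rose in 10 of 11 measured genes (camera, adjusted p = 1.6e-04, but 0.22 with estimated correlation), led by Hoxb1 (4.21 ± 0.15). Those of groups 5 to 13 went both ways (4 of 15 rose, 9 fell; camera, adjusted p = 0.87), with Hoxd9 (3.75 ± 0.12) and Hoxc6 (-1.74 ± 0.19).

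Other large rises in T+ cells were the NODAL co-receptor Cfc1 (8.09 ± 0.07), the apelin receptor Aplnr (6.75 ± 0.06), the prostaglandin synthase Ptgds (6.7 ± 0.13), Msx1 (6.46 ± 0.08) and Mogat2 (6.08 ± 0.07). The retinaldehyde dehydrogenase Aldh1a2, which makes retinoic acid, rose from 3.11 ± 0.414 to 270.2 ± 19.3 TPM (6.05 ± 0.10), while the retinoic acid pathway as a list did not pass (camera, adjusted p = 0.56). Endoderm genes were already raised in this population: of the definitive endoderm list, 11 of its 14 measured members rose, 2 fell and 1 did not pass the test (camera, adjusted p = 4.4e-04, but 0.24 with estimated correlation). The list included Gata4 (4.52 ± 0.06), Cxcr4 (4.17 ± 0.18) and Gata6 (3.78 ± 0.06). The epithelial list split, with 4 of 12 genes higher and 6 lower. Krt8 (3.59 ± 0.09) rose and the adhesion gene Cdh1 (-2.4 ± 0.08) fell, and the list's median of -0.14 changed sign under quantile normalization. Of the mesenchymal list 6 of 10 rose and 3 fell (camera, adjusted p = 0.10). These included Cdh2 (2.5 ± 0.10) and Twist1 (2.01 ± 0.14). All 14 naive pluripotency genes fell (camera, adjusted p = 1.6e-05, and 0.046 with estimated correlation). All 11 general pluripotency genes fell too (camera, adjusted p = 1.8e-04, but 0.10 with estimated correlation). Among them were Utf1 (-8.04 ± 0.11), Dppa5a (-8.02 ± 0.27) and Tdh (-7.84 ± 0.10). The BMP pathway rose in 9 of 9 genes (camera, adjusted p = 1.6e-05, but 0.10 with estimated correlation) and the WNT targets in 9 of 10, with 1 lower (camera, adjusted p = 3.7e-04, but 0.14 with estimated correlation), including Lef1 (3.04 ± 0.08) and Axin2 (2.5 ± 0.06).

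The feeder fibroblast list fell in 13 of 14 genes and 1 rose (camera, adjusted p = 4.4e-04, but 0.35 with estimated correlation). Thbs1 (-8.32 ± 0.13), Spp1 (-8.22 ± 0.14), S100a6 (-8.47 ± 0.15) and Anxa1 (-8.14 ± 0.08) were among the largest falls. S100a4 was listed at 0 in 2 of the T+ libraries and stood at 265 ± 19.8 TPM in mESC. By limma, 13520 of 16097 tested genes were called, 5547 higher and 7973 lower. Of these, 4919 changed at least 2-fold (1668 higher, 3251 lower). The share of called genes that were higher was 41% as deposited and 53.4% with quantile normalization, with all-gene medians of -0.17 and 0.07. Mitochondrially encoded transcripts made up 6.53 ± 0.256% of the TPM in T+. The list of these genes was called higher (camera, adjusted p = 6.9e-04, but 0.37 with estimated correlation), a call that ended with quantile normalization (adjusted p = 0.28).

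Double-positive cells were compared with mESC to describe cells carrying both reporters. Endoderm and streak genes were both raised in them. Of the definitive endoderm list, 13 of its 14 measured members rose, 0 fell and 1 did not pass the test (camera, adjusted p = 2.2e-06, but 0.12 with estimated correlation), with Sox17 (6.42 ± 0.14), Krt18 (5.27 ± 0.08) and Foxa2 (4.95 ± 0.22). All 11 primitive streak genes rose (camera, adjusted p = 7.5e-05, but 0.31 with estimated correlation). Examples were T (4.74 ± 0.24), Fgf8 (3.65 ± 0.22) and Lhx1 (3.23 ± 0.17). All 8 node and notochord genes rose (camera, adjusted p = 0.0011, but 0.33 with estimated correlation). The list included Shh (4.1 ± 0.34) and Nog (3.09 ± 0.16). Of the paraxial mesoderm list, 7 of its 11 measured members rose, 2 fell and 2 did not pass the test (camera, adjusted p = 0.0091, but 0.12 with estimated correlation). These included Mesp1 (4.62 ± 0.16) and Msgn1 (3.47 ± 0.18). The lateral and cardiac list rose in 7 of 9, with 1 lower (camera, adjusted p = 7.2e-04, but 0.12 with estimated correlation). Hand1 (8.15 ± 0.07), Cfc1 (7.96 ± 0.07), Tmprss2 (6.63 ± 0.08), Msx1 (6.52 ± 0.08), Mogat2 (6.31 ± 0.07), Aplnr (5.89 ± 0.06) and Dkk1 (5.86 ± 0.13) were the other largest rises, and Tmprss2 stood at 106 ± 11.7 TPM. Of the epithelial list, 8 of its 12 measured members rose and 4 fell (camera, adjusted p = 0.0062, but 0.31 with estimated correlation). Of the endothelial list 9 of its 11 measured members rose and 2 fell (camera, adjusted p = 0.0062, but 0.31 with estimated correlation). The primitive blood list rose in 6 of 7 genes (camera, adjusted p = 0.024, but 0.46 with estimated correlation), a call that ended with median-of-ratios scaling (adjusted p = 0.057) and with quantile normalization (adjusted p = 0.064). Hbb-bh1 was listed at 1.66, 2.56 and 5.14 TPM in the double-positive libraries and at 0 in mESC.

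All 14 naive pluripotency genes fell in double-positive cells (camera, adjusted p = 7.7e-06, but 0.095 with estimated correlation). Of the general list 10 of its 11 measured members fell and 1 rose (camera, adjusted p = 7.2e-04, but 0.12 with estimated correlation). Dppa5a (-8.7 ± 0.27), Utf1 (-8.32 ± 0.11), Dnmt3l (-8.18 ± 0.09), Spp1 (-8.29 ± 0.14), S100a6 (-8.36 ± 0.15) and Anxa1 (-8.15 ± 0.08) were among the largest falls. S100a4 was listed at 0 in every double-positive library, and the feeder list fell in 13 of 14 genes and rose in 1 (camera, adjusted p = 4.7e-04, but 0.31 with estimated correlation). By limma, 13721 of 16097 tested genes were called, 5618 higher and 8103 lower. Of these, 4877 changed at least 2-fold (1613 higher, 3264 lower). The share of called genes that were higher was 40.9% as deposited and 53.2% with quantile normalization, with all-gene medians of -0.19 and 0.06. Mitochondrially encoded transcripts made up 6.51 ± 0.398% of the TPM.

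SOX17+ cells were compared with T+ cells to describe what separates the single-positive populations. Most genes of the definitive endoderm and epithelial lists were higher in SOX17+ cells, and most of the paraxial mesoderm, HOX paralogs 1 to 4 and mesenchymal lists were higher in T+ cells. Of the epithelial list, 11 of its 12 measured members rose and 1 fell (camera, adjusted p = 2.1e-09, but 0.099 with estimated correlation). Among them were Cldn7 (3.93 ± 0.07), Crb3 (3.89 ± 0.11) and Epcam (2.73 ± 0.05). Of the definitive endoderm list, 12 of its 14 measured members rose, 1 fell and 1 did not pass the test (camera, adjusted p = 5.2e-07, but 0.14 with estimated correlation). Among them, Foxa1 (3.82 ± 0.19) and Sox17 (4.37 ± 0.14) were higher. All 11 paraxial mesoderm genes were lower (camera, adjusted p = 7.6e-09, and 0.0056 with estimated correlation). Mesp1 fell from 78.2 ± 14.9 to 0.94 ± 0.452 TPM (-5.36 ± 0.16), and Msgn1 (-5.44 ± 0.18), Dll3 (-4.0 ± 0.11) and Tbx6 (-3.87 ± 0.16) fell with it. Of the HOX paralogs 1 to 4, 10 of 11 were lower and 1 did not pass the test (camera, adjusted p = 1.7e-06, but 0.15 with estimated correlation), led by Hoxa3 (-2.9 ± 0.13) and Hoxb1 (-2.76 ± 0.15). HOX paralogs 5 to 13 did not pass as a list, with 2 of 15 genes higher and 9 lower (camera, adjusted p = 0.081). The mid and hindgut endoderm list did not pass either, with 0 of 8 genes higher and 7 lower (camera, adjusted p = 0.059). Of the mesenchymal list 9 of 10 were lower and 1 did not pass (camera, adjusted p = 9.7e-05, but 0.18 with estimated correlation), among them the transcriptional repressors of epithelial genes Snai1 (-2.45 ± 0.09) and Zeb2 (-1.72 ± 0.14) and the bHLH factor Twist1 (-2.17 ± 0.14).

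The extraembryonic endoderm list was higher in SOX17+ cells in 10 of 12 measured genes, and 2 did not pass (camera, adjusted p = 3.0e-06, and 0.033 with estimated correlation). The retinol and thyroxine carrier transthyretin, Ttr, stood at 73.5 ± 8.33 TPM in SOX17+ and 1.22 ± 0.578 TPM in T+ (5.09 ± 0.15), and Hnf4a (4.29 ± 0.08) and Apom (3.14 ± 0.13) were higher too. Blood and endothelial genes were higher in the same libraries. All 7 primitive blood genes were higher (camera, adjusted p = 5.7e-06, but 0.18 with estimated correlation). Hbb-bh1 was listed at 51.9, 75.8 and 141 TPM in SOX17+ replicates 1, 2 and 3 and at 1.06, 1.64 and 1.31 TPM in T+ (5.16 ± 0.36), and Hba-x (4.54 ± 0.34) and Gata1 (2.78 ± 0.17) were higher as well. Of the endothelial list, 8 of 11 were higher and 3 lower (camera, adjusted p = 3.1e-04, but 0.18 with estimated correlation), with Cdh5 (3.33 ± 0.10), Tie1 (3.25 ± 0.12) and Flt1 (2.84 ± 0.10) higher and Lmo2 (-0.53 ± 0.11) lower. Of the anterior gut list, 6 of its 8 measured members were higher, 1 was lower and 1 did not pass the test (camera, adjusted p = 0.0043, but 0.18 with estimated correlation), with Nkx2-1 (3.71 ± 0.10) and Pax9 (2.14 ± 0.09) higher and Lefty1 (-2.93 ± 0.19) lower. The other largest differences toward SOX17+ were the protease inhibitor Spink1, at 663 ± 16.9 against 10.4 ± 2.6 TPM (5.89 ± 0.13), Clic6 (5.25 ± 0.10) and the carboxypeptidase Cpn1 (4.94 ± 0.11). The alpha-defensin family gene Defa30 was listed at 0 in all T+ libraries, at 78.3, 71.8 and 69.9 TPM in SOX17+ and at 76.2, 74.9 and 0 TPM in double-positive replicates 1, 2 and 3.

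Of the signalling lists, only the NODAL pathway list was called between these populations, and not with estimated correlation. Of the NODAL pathway list, 6 of 10 were lower in SOX17+ and 4 did not pass (camera, adjusted p = 0.0065, but 0.34 with estimated correlation), with the inhibitors Lefty2 (-4.18 ± 0.15) and Lefty1 (-2.93 ± 0.19) and the co-receptor Tdgf1 (-3.57 ± 0.17). The WNT targets did not pass, with 3 of 10 genes higher and 6 lower (camera, adjusted p = 0.45), nor did the BMP pathway, with 5 of 9 genes higher and 2 lower or 6 higher adjusted over the list alone (camera, adjusted p = 0.40). Of the primitive streak list 8 of 11 were lower and 2 higher (camera, adjusted p = 0.0065, but 0.49 with estimated correlation), with T (-5.25 ± 0.24), Fgf8 (-3.22 ± 0.22) and Wnt3 (-2.1 ± 0.09), and of the axial progenitor list 8 of 10 were lower (camera, adjusted p = 0.0018, but 0.33 with estimated correlation). Examples were Wnt3a (-1.55 ± 0.18). The node and notochord list was lower in 7 of 8 genes and higher in 1 (camera, adjusted p = 0.010, but 0.52 with estimated correlation). The gene that was higher, Foxa2 (1.68 ± 0.22), also belongs to the endoderm list. Aldh1a2 fell from 270.2 ± 19.3 to 4.39 ± 0.67 TPM (-5.66 ± 0.10), Ptgds from 251 ± 13.6 to 3.34 ± 0.625 TPM (-5.87 ± 0.13). The retinoic acid binding protein Crabp2 (-2.49 ± 0.18) fell, although the retinoic acid list did not pass (camera, adjusted p = 0.064). The lateral and cardiac mesoderm list was lower in 6 of 9 genes and higher in 1 (camera, adjusted p = 0.014, but 0.18 with estimated correlation), with Bmp4 (-2.17 ± 0.04) and Foxf1 (-1.81 ± 0.09), and Hand1 remained at 265 ± 16 TPM in SOX17+. Of the cell cycle list 11 of 15 were lower and 4 did not pass (camera, adjusted p = 9.7e-05, but 0.18 with estimated correlation). The list included Top2a (-0.98 ± 0.04) and Mki67 (-0.97 ± 0.18). By limma, 8767 of 16097 tested genes were called, 4092 higher and 4675 lower. Of these, 1392 changed at least 2-fold (797 higher, 595 lower). Higher genes made up 46.7% of the called genes as deposited, 50.1% with median-of-ratios scaling and 44.7% with quantile normalization, so which direction held more genes depended on the scaling.

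**Figure D2:**
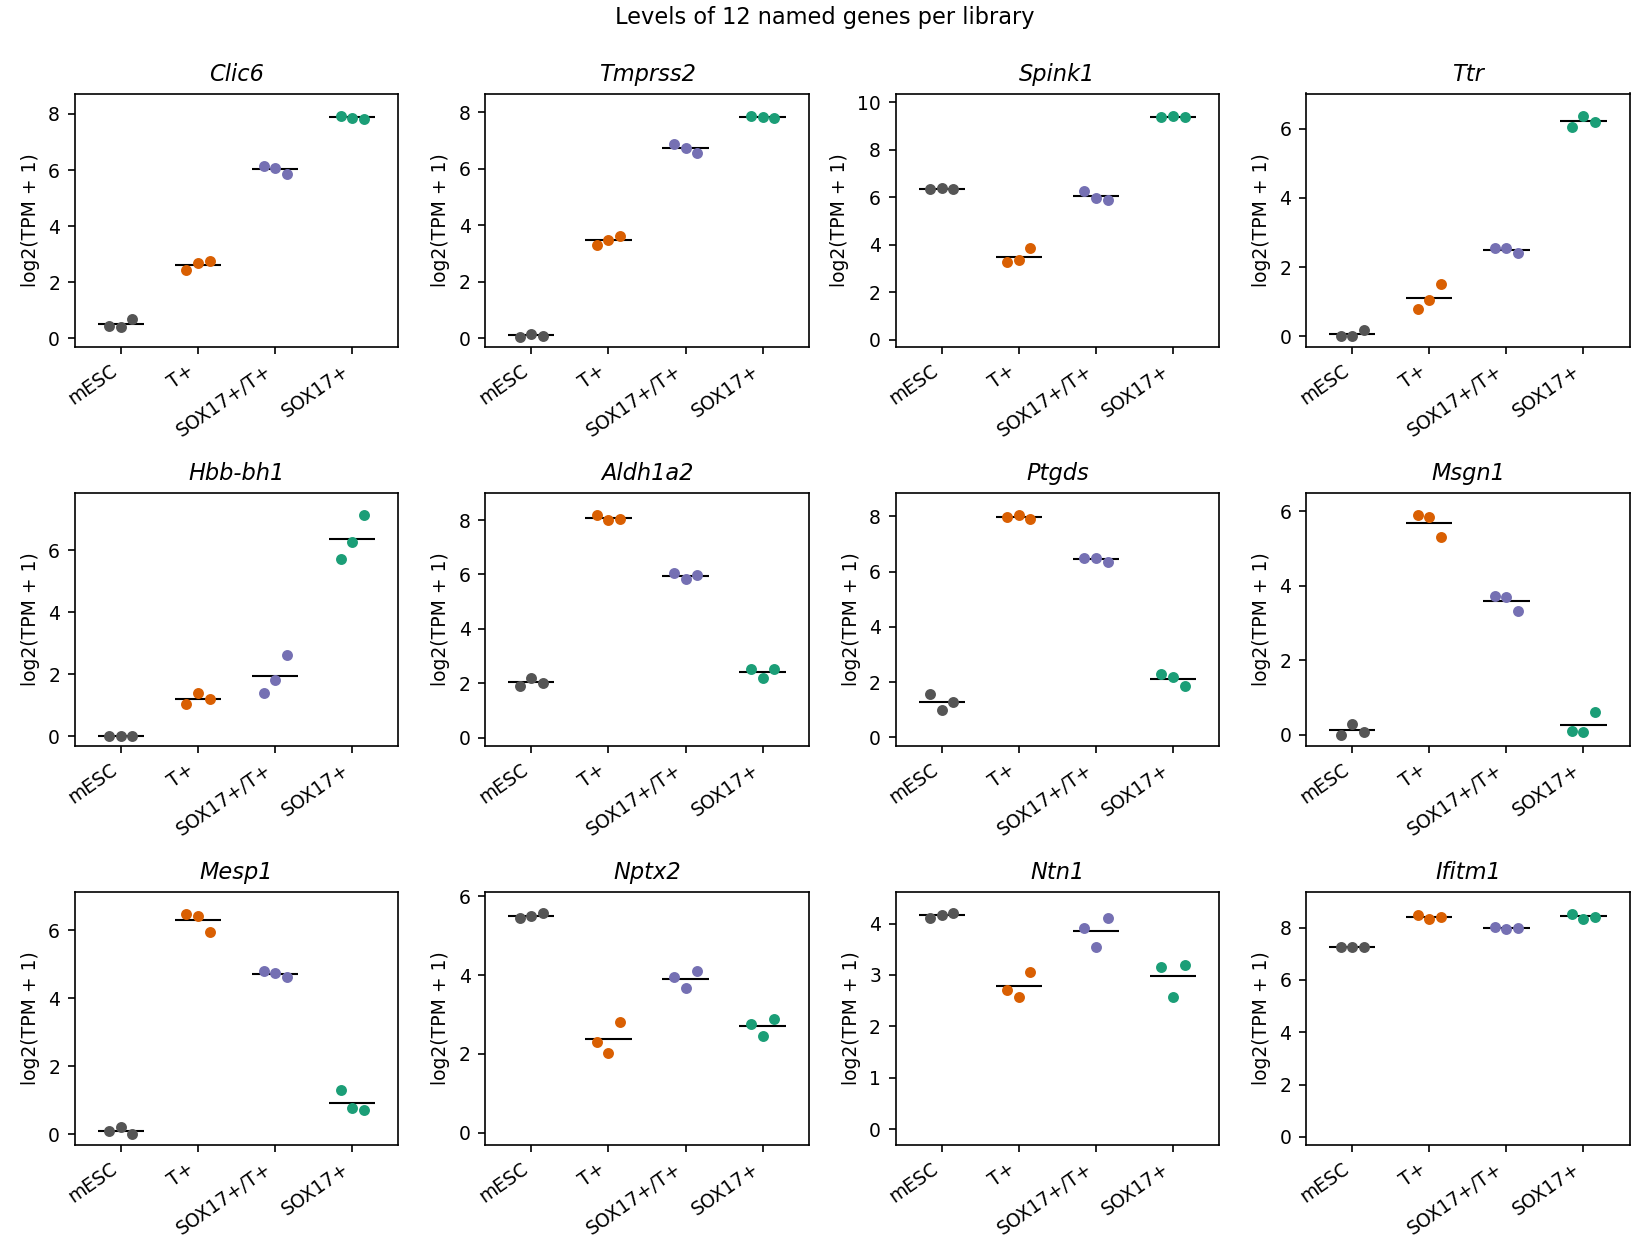
Levels of 12 named genes as log2(TPM + 1) in the 4 groups, with points for single libraries and short lines for group means. Clic6, Tmprss2 and Spink1 rose from T+ through double-positive to SOX17+, Aldh1a2, Ptgds, Msgn1 and Mesp1 fell along the same order, Ttr and Hbb-bh1 were low in double-positive cells, and Nptx2, Ntn1 and Ifitm1 had double-positive levels outside those of both single-positive groups.

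Double-positive cells were compared with T+ cells to describe what distinguishes T+ cells that also carry the SOX17 reporter. The epithelial list was higher in double-positive cells in 11 of 12 genes, and 1 did not pass (camera, adjusted p = 4.1e-17, and 0.028 with estimated correlation). These included Crb3 (2.74 ± 0.11), Cldn7 (2.68 ± 0.07), Cldn6 (2.07 ± 0.09) and Krt18 (1.74 ± 0.08). Of the definitive endoderm list, 11 of its 14 measured members rose, 0 fell and 3 did not pass the test (12 rose and 0 fell adjusted over the list alone) (camera, adjusted p = 9.2e-12, and 0.045 with estimated correlation). Among them, Sox17 (3.65 ± 0.14) and Foxa1 (2.41 ± 0.19) were higher. All 11 paraxial mesoderm genes were lower (camera, adjusted p = 1.8e-10, and 0.0033 with estimated correlation). Among them were Msgn1 (-2.11 ± 0.18), Tbx6 (-2.04 ± 0.16) and Mesp1 (-1.57 ± 0.16). Mesp1 nevertheless remained at 25.4 ± 1.41 TPM. All 11 measured HOX paralogs 1 to 4 were lower (camera, adjusted p = 9.0e-09, but 0.092 with estimated correlation), with Hoxa2 (-1.58 ± 0.09) and Hoxb1 (-1.53 ± 0.15), as were 9 of 15 HOX paralogs 5 to 13, with 6 not called (11 adjusted over the list alone; camera, adjusted p = 1.6e-04, but 0.23 with estimated correlation).

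The pepsinogen gene Pga5 (3.63 ± 0.22), Clic6 (3.4 ± 0.10) and Tmprss2 (3.26 ± 0.08), the myosin light chain Myl3 (3.03 ± 0.18) and the glutathione peroxidase Gpx2 (3.01 ± 0.21) were among the largest rises. Trh, which encodes thyrotropin-releasing hormone, stood at 407 ± 106 TPM against 32.6 ± 11.6 TPM in T+ and 262 ± 12 TPM in mESC (3.62 ± 0.26). The largest falls were Lefty2 (-2.38 ± 0.15), Aldh1a2 (-2.13 ± 0.10), Igfbp3 (-2.02 ± 0.16), Pou5f1 (-1.82 ± 0.11), Pcdh19 (-1.76 ± 0.10) and Sprr2a2 (-1.74 ± 0.11) besides Msgn1 and Tbx6, and Pou5f1 (Oct4) remained at 25.1 ± 2.4 TPM. Of the NODAL pathway list, 6 of its 10 measured members fell, 0 rose and 4 did not pass the test (1 rose and 6 fell adjusted over the list alone) (camera, adjusted p = 0.019, but 0.39 with estimated correlation). Of the mesenchymal list 6 of 10 fell and 4 did not pass (camera, adjusted p = 0.0028, but 0.24 with estimated correlation). Examples were Snai1 (-1.19 ± 0.09) and Twist1 (-1.1 ± 0.14). Of the mid and hindgut list, 6 of its 8 measured members fell, 0 rose and 2 did not pass the test (0 rose and 8 fell adjusted over the list alone) (camera, adjusted p = 0.0027, but 0.32 with estimated correlation). The list included Cdx1 (-0.74 ± 0.16) and Cdx2 (-0.72 ± 0.14). Endothelial and blood genes were higher beside the endoderm genes. Of the endothelial list 8 of 11 were higher and 3 lower (camera, adjusted p = 1.4e-04, but 0.20 with estimated correlation), with Flt1 (2.38 ± 0.10) and Cdh5 (1.87 ± 0.10), and of the primitive blood list 5 of 7 were higher and 2 did not pass (camera, adjusted p = 3.1e-04, but 0.25 with estimated correlation). These included Gata1 (2.25 ± 0.17) and Itga2b (1.1 ± 0.11). Hbb-bh1 was not called, at 3.12 ± 1.8 TPM against 1.34 ± 0.291 TPM. Of the lateral and cardiac list 6 of 9 were lower and 1 higher (camera, adjusted p = 0.0022, but 0.14 with estimated correlation), and of the axial progenitor list 8 of 10 were lower and 2 did not pass (9 lower adjusted over the list alone; camera, adjusted p = 2.2e-04, but 0.23 with estimated correlation). The anterior gut list was higher in 4 of 8 and lower in 1 (camera, adjusted p = 0.015, but 0.21 with estimated correlation), the extraembryonic endoderm list higher in 5 of 12 and lower in 1 (camera, adjusted p = 0.019, but 0.21 with estimated correlation) and the glycolysis list higher in 3 of 14 (camera, adjusted p = 0.0097, but 0.56 with estimated correlation). The cell cycle list was lower in 11 of 15 genes, and 4 did not pass (12 lower adjusted over the list alone; camera, adjusted p = 1.4e-04, but 0.21 with estimated correlation), and the dissociation stress list was higher in 2 of 10, and 8 did not pass (5 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.036, but 0.23 with estimated correlation). By limma, 4578 of 16097 tested genes were called, 2034 higher and 2544 lower. Of these, 403 changed at least 2-fold (285 higher, 118 lower). Higher genes made up 44.4% of the called genes as deposited, 52.2% with median-of-ratios scaling and 47.4% with quantile normalization, so which direction held more genes depended on the scaling. Libraries of these groups that share a replicate number resembled each other beyond their group. With the replicate number as a block over all 12 libraries, 5202 genes were called. That block sets the same replicate shift in all 4 groups, so it is not a pairing of these groups alone.

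SOX17+ cells were compared with double-positive cells to describe SOX17 reporter cells without and with the T reporter. The extraembryonic endoderm list was higher in SOX17+ cells in 10 of 12 genes, and 2 did not pass (camera, adjusted p = 2.0e-08, and 0.011 with estimated correlation). Ttr stood at 73.5 ± 8.33 TPM against 4.69 ± 0.366 TPM (3.71 ± 0.15), and Apom (2.71 ± 0.13), Hnf4a (2.23 ± 0.08) and Apoa1 (1.4 ± 0.08) were higher. All 7 primitive blood genes were higher in the same libraries (camera, adjusted p = 3.3e-06, but 0.21 with estimated correlation). Among them were Hbb-bh1 (4.42 ± 0.36), Hba-x (3.33 ± 0.34) and Klf1 (2.01 ± 0.13). The adult alpha-globins Hba-a1 (3.0 ± 0.29) and Hba-a2 (2.96 ± 0.30), near-identical genes whose reads cannot be assigned with certainty to 1 copy, were higher too. Of the endothelial list, 9 of 11 were higher, 1 was lower and 1 did not pass (camera, adjusted p = 1.4e-05, but 0.16 with estimated correlation). Examples were Cdh5 (1.46 ± 0.10), Tie1 (1.45 ± 0.12) and Tal1 (1.44 ± 0.11). The paraxial mesoderm list was lower in 10 of 11 genes, and 1 did not pass (camera, adjusted p = 1.0e-09, and 0.0036 with estimated correlation). The list included Mesp1 (-3.79 ± 0.16), Msgn1 (-3.33 ± 0.18), Dll3 (-2.46 ± 0.11) and Rspo3 (-2.38 ± 0.09). Of the primitive streak list, 7 of its 11 measured members were lower, 0 was higher and 4 did not pass the test (0 was higher and 8 were lower adjusted over the list alone) (camera, adjusted p = 4.3e-05, but 0.26 with estimated correlation), with T (-3.73 ± 0.24), Fgf8 (-2.35 ± 0.22) and Wnt3 (-1.27 ± 0.09), and of the node and notochord list 7 of 8 were lower and 1 did not pass (camera, adjusted p = 7.9e-04, but 0.37 with estimated correlation). These included Nog (-1.45 ± 0.16) and Foxj1 (-1.32 ± 0.22).

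Single genes higher in SOX17+ cells included Spink1, at 663 ± 16.9 against 64.8 ± 8.48 TPM (3.34 ± 0.13), the folate receptor Folr1 (2.8 ± 0.08) and the dipeptidase Dpp4 (2.72 ± 0.11). Ptgds fell from 86.3 ± 5.79 to 3.34 ± 0.625 TPM (-4.34 ± 0.13), and Aldh1a2 (-3.53 ± 0.10), Scara3 (-2.79 ± 0.13) and Tdgf1 (-2.67 ± 0.17) were also among the largest falls. The definitive endoderm list was higher in 10 of 14 genes and lower in 2 (camera, adjusted p = 7.9e-04, but 0.25 with estimated correlation), with Foxa1 (1.41 ± 0.19). The anterior gut list was higher in 6 of 8 and lower in 1 (camera, adjusted p = 0.0020, but 0.16 with estimated correlation). Among them were Nkx2-1 (2.63 ± 0.10) and Pax9 (1.3 ± 0.09). Of the epithelial list 11 of 12 were higher and 1 did not pass (camera, adjusted p = 8.6e-07, but 0.16 with estimated correlation), with Cldn7 (1.25 ± 0.07) and Epcam (1.12 ± 0.05), and of the mesenchymal list 9 of 10 were lower and 1 did not pass (camera, adjusted p = 1.1e-05, but 0.16 with estimated correlation). Examples were Snai1 (-1.26 ± 0.09) and Cdh2 (-0.93 ± 0.10). HOX paralogs 1 to 4 were lower in 7 of 11 genes, and 4 did not pass (camera, adjusted p = 1.2e-04, but 0.21 with estimated correlation). The list included Hoxa3 (-1.42 ± 0.13). HOX paralogs 5 to 13 did not move as a list (4 of 15 higher, 2 lower; camera, adjusted p = 0.78). By limma, 5894 of 16097 tested genes were called, 3189 higher and 2705 lower. Of these, 437 changed at least 2-fold (260 higher, 177 lower). Higher genes made up 54.1% of the called genes as deposited, 52.1% with median-of-ratios scaling and 47.5% with quantile normalization, so which direction held more genes depended on the scaling.

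**Figure D3:**
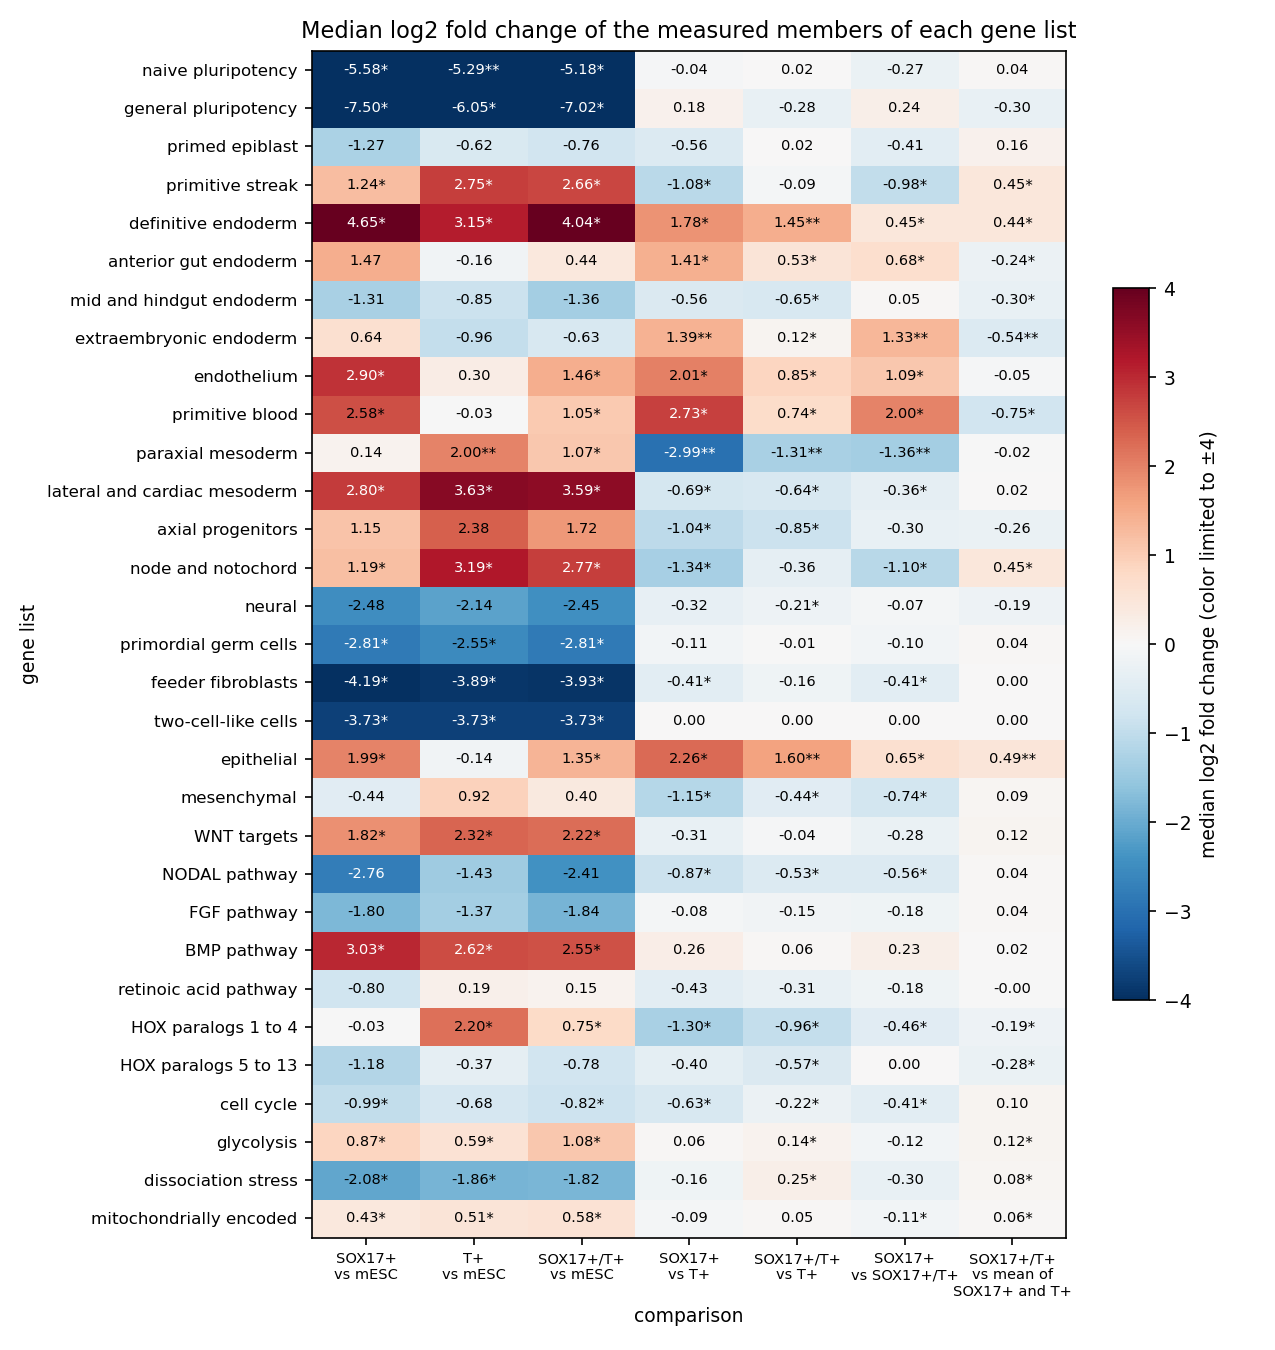
Heat map of the median log2 fold change of the measured members of each of the 31 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with blue for negative and red for positive medians, 1 asterisk for a camera adjusted p under 0.05 with the preset correlation, and a double asterisk for one that also held with an estimated correlation. The double asterisks fell on paraxial mesoderm in 4 comparisons, extraembryonic endoderm in 3, epithelial genes in 2 and naive pluripotency and definitive endoderm in 1 each.

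Double-positive cells were then tested against the midpoint of the log2 values of T+ and SOX17+ cells, to ask where they depart from that point on the log2 scale. An equal mixture of both populations adds in TPM and would lie above this midpoint wherever the populations differ, so the sides were also compared in linear TPM, a check chosen after the results were seen. Of the 713 genes called above the midpoint, 73 were not above the mean of both groups in linear TPM, while all 876 called below it were below that mean. The epithelial list lay above the midpoint in 11 of 12 genes, and 1 did not pass (camera, adjusted p = 1.1e-15, and 0.037 with estimated correlation). These included Crb3 (0.80 ± 0.10), Cldn7 (0.72 ± 0.06) and Krt18 (0.66 ± 0.07), but 5 of the 11, Crb3 and Cldn7 among them, were not above the linear mean. The extraembryonic endoderm list lay below it: 6 of 12 genes were called lower, 0 higher and 6 were not called (8 lower adjusted over the list alone; camera, adjusted p = 6.1e-08, and 0.027 with estimated correlation), with Apom (-1.15 ± 0.11) and Ttr (-1.16 ± 0.13, adjusted p = 2.0e-04, and adjusted p = 0.054 with a pseudocount of 0.1). Definitive endoderm genes lay above it in 6 of 14 and below in 1 (8 and 1 adjusted over the list alone; camera, adjusted p = 2.7e-08, but 0.12 with estimated correlation), with Sox17 (1.46 ± 0.12). Of the 6 above, 4 were also above the linear mean. Primitive streak genes lay above it in 6 of 11 and below in 1 (8 and 1 adjusted over the list alone; camera, adjusted p = 3.5e-04, but 0.45 with estimated correlation). Among them was T (1.11 ± 0.21), which like 1 other of the 6 was not above the linear mean. T and Sox17 are the genes of the sort reporters. Their side of the midpoint can follow from the gates alone, so they are no evidence on the lists that count them as members. Primitive blood genes lay below it in 5 of 7 and above in 1 (6 and 1 adjusted over the list alone; camera, adjusted p = 0.0021, but 0.45 with estimated correlation), a call that ended with a pseudocount of 0.1 (adjusted p = 0.10). The largest fall was Hbb-bh1 (-1.84 ± 0.31). The anterior gut list lay below it in 3 of 8 genes and above in 0 (5 and 0 adjusted over the list alone; camera, adjusted p = 0.0094, but 0.29 with estimated correlation), and the mid and hindgut list also in 3 of 8 and above in 0 (4 and 0 adjusted over the list alone; camera, adjusted p = 0.011, but 0.45 with estimated correlation). HOX paralogs 5 to 13 lay below it in 6 of 15 and above in 0 (8 and 0 adjusted over the list alone; camera, adjusted p = 3.5e-04, but 0.40 with estimated correlation), and HOX paralogs 1 to 4 in 3 of 11 and above in 0 (4 and 1 adjusted over the list alone; camera, adjusted p = 0.011, but 0.45 with estimated correlation). With a pseudocount of 0.1 the calls of the anterior gut list (adjusted p = 0.40) and of HOX paralogs 1 to 4 (adjusted p = 0.48) ended. The dissociation stress list lay above it in 3 of 10 and below in 0 (4 and 0 adjusted over the list alone; camera, adjusted p = 0.0089, but 0.29 with estimated correlation). The node and notochord list lay above it in 2 of 8 (3 adjusted over the list alone; camera, adjusted p = 0.0021, but 0.45 with estimated correlation), and 1 of these 2 was not above the linear mean. The mitochondrially encoded list lay above it in 2 of 13 (3 adjusted over the list alone; camera, adjusted p = 0.0026, but 0.45 with estimated correlation), a call that ended with quantile normalization (adjusted p = 0.096). The glycolysis list was called higher with 0 of its 14 genes called (camera, adjusted p = 0.0017, but 0.45 with estimated correlation). The other largest rises over the midpoint were Pga5 (2.25 ± 0.19), Trh (1.77 ± 0.22), Eras (1.69 ± 0.08), Ptgds (1.4 ± 0.12) and Nptx2 (1.38 ± 0.16). Of these, Ptgds, at 86.3 ± 5.79 TPM against 251 ± 13.6 in T+ and 3.34 ± 0.625 in SOX17+, was below the linear mean. The other largest falls were Folr1 (-1.1 ± 0.07), Hba-a1 (-1.41 ± 0.25) and Hba-a2 (-1.45 ± 0.26).

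By limma, 1589 of 16097 tested genes were called, 713 higher and 876 lower. Of these, 36 changed at least 2-fold (23 higher, 13 lower). The share of called genes above the midpoint was 44.9% as deposited, 54.1% with median-of-ratios scaling and 55.9% with quantile normalization, so which side held more genes depended on the scaling. The count fell to 829 without double-positive replicate 1, to 887 without double-positive replicate 2 and to 1056 without the filter on low values.

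Some genes lay outside both single-positive groups in double-positive cells. The secreted pentraxin Nptx2 was highest there among the sorted groups, at 14.2 ± 2.23 TPM against 4.31 ± 1.5 in T+ and 5.56 ± 0.994 in SOX17+. The axon guidance gene netrin 1, Ntn1, stood at 13.7 ± 2.8 TPM against 5.94 ± 1.27 in T+ and 7.0 ± 1.76 in SOX17+. Pga5 stood at 15 ± 4.36 TPM against 0.261 ± 0.138 in T+ and 7.76 ± 2.39 in SOX17+. The non-coding RNA Bc1 and the genes AW551984 and Asb4 were above both groups as well, at 176 ± 25.5, 44.4 ± 5.89 and 11.7 ± 1.31 TPM. The interferon-induced transmembrane genes Ifitm1 and Ifitm3 were lowest in double-positive cells among the sorted groups, Ifitm1 at 255 ± 5.51 TPM against 339.5 ± 14.8 in T+ and 345 ± 23.2 in SOX17+. Ifitm3 stood at 19.2 ± 0.975 TPM against 26.8 ± 1.71 in T+ and 26.7 ± 2.02 in SOX17+. The homeobox gene Pitx1 stood at 7.53 ± 1.44 TPM against 12.3 ± 2.51 in T+ and 11.4 ± 0.185 in SOX17+. The guidance receptor Robo1, Nup62cl and the glutathione transferase Gstm2 were also below both groups, at 7.46 ± 0.30, 6.28 ± 0.346 and 7.44 ± 0.999 TPM. In all, 260 of 16097 genes were called beyond both groups, 118 above and 142 below, and 3 of them by at least 2-fold on each side. With median-of-ratios scaling 154 were above and 119 below, and with quantile normalization 160 above and 121 below, so which side held more genes depended on the scaling. The count was 166 without double-positive replicate 1. Far more genes changed in steps: 1309 were called higher both in double-positive than in T+ cells and in SOX17+ than in double-positive cells, and 1223 were called lower at both steps, of which 102 and 58 changed at least 2-fold at each step. Clic6 and Tmprss2 rose and Mesp1, Msgn1 and Aldh1a2 fell in this way.

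Placed on the axis from the T+ mean (0) to the SOX17+ mean (1) over the 1392 genes that differed between them by at least 2-fold, the double-positive libraries lay at 0.507, 0.487 and 0.455, a mean of 0.483 ± 0.0261 (SD, n = 3). For the 797 genes higher in SOX17+ cells the position was 0.511 ± 0.0282, and for the 595 genes higher in T+ cells it was 0.437 ± 0.0283. A mixture adds in TPM and so lies nearer the higher group on the log2 scale. That alone would move these positions apart in this direction, so they do not show that the gene sets differ. The undifferentiated libraries, which are not on the way between these groups, lay at 0.378 to 0.381 on the same axis, so a value near the middle does not by itself mark an intermediate. No test was run on the position.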

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

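The tests on scaling to a fixed total, on T+ cells in the SOX17+ gate, on reads shared between globin genes and on a mixture in 1 proportion were chosen after the results were seen. Some genes moved in opposite directions from mESC in the single-positive populations, by at least 2-fold each way and with a called difference between SOX17+ and T+ in the limma test. There were 23 genes above mESC in SOX17+ and below it in T+, and 8 genes with the opposite course. Of the first kind, Spink1 stood at 663 ± 16.9, 80.7 ± 1.45 and 10.4 ± 2.6 TPM in SOX17+, mESC and T+ (5.89 ± 0.13 between SOX17+ and T+, adjusted p = 4.0e-11). Cpn1 stood at 72.4 ± 4.79, 5.15 ± 0.308 and 1.39 ± 0.19 TPM in SOX17+, mESC and T+ (4.94 ± 0.11 between SOX17+ and T+, adjusted p = 2.2e-12). Dpp4 stood at 29.4 ± 0.827, 4.78 ± 0.363 and 0.462 ± 0.0932 TPM in SOX17+, mESC and T+ (4.38 ± 0.11 between SOX17+ and T+, adjusted p = 4.8e-12). Gpx2 stood at 41.9 ± 7.17, 7.82 ± 0.753 and 1.13 ± 0.50 TPM in SOX17+, mESC and T+ (4.35 ± 0.21 between SOX17+ and T+, adjusted p = 1.0e-08). Of the second kind, Mfap4 stood at 1.49 ± 0.228, 5.8 ± 1.33 and 26.3 ± 1.73 TPM in SOX17+, mESC and T+ (-3.45 ± 0.12 between SOX17+ and T+, adjusted p = 1.1e-10). Dll1 stood at 1.66 ± 0.14, 5.77 ± 0.225 and 20.3 ± 3.16 TPM in SOX17+, mESC and T+ (-2.99 ± 0.10 between SOX17+ and T+, adjusted p = 7.8e-11). Mcub stood at 1.35 ± 0.324, 4.27 ± 0.67 and 16.8 ± 2.39 TPM in SOX17+, mESC and T+ (-2.92 ± 0.14 between SOX17+ and T+, adjusted p = 2.3e-09). Gna14 stood at 1.22 ± 0.19, 3.68 ± 0.238 and 13.8 ± 0.595 TPM in SOX17+, mESC and T+ (-2.74 ± 0.09 between SOX17+ and T+, adjusted p = 5.0e-11). These were the 4 largest differences each way among genes with a mean of at least 10 TPM in some group and a symbol that is not a predicted gene, RIKEN clone or bare identifier. Of them, Mfap4, Mcub and Gna14 were chosen after their values were seen. The mESC levels of all these genes may include feeder RNA, which was not separated here.

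Fibroblast genes were high in the mESC libraries, with Acta2 at 1006 ± 127 TPM and Tagln at 722 ± 77.7 TPM as the most abundant of the fixed list. Of a second list of 14 fibroblast genes, written before its values were seen, 12 (85.7%) were called higher in mESC than in each sorted group, not Fstl1 and Gas1. Of these 12, 10 also had means above 1 TPM in each sorted group. Over all 16097 tested genes, 8042, 7973 and 8103 were called higher in mESC than in SOX17+, T+ and SOX17+/T+. Called fibroblast genes also moved together between the mESC libraries, over a range of 0.33 on the log2 scale against a median of 0.0324 for random lists (percentile 100 of 10000 lists). The random lists were matched on mean level and not on correlation between genes. The range therefore does not tell a varying share of feeders from genes that vary together within the stem cells. Xist, chosen after its values were seen, was listed at 0.433, 0.52 and 0.476 TPM in mESC and at 0.0322 TPM or less in each sorted library. Scaling to a fixed total is argued against as the whole cause, since a shift of scale moves genes alike. All-gene medians against mESC were -0.17 to -0.19 as deposited and 0.05 to 0.07 with quantile normalization. The median of the feeder list stayed at -3.64 or lower in each comparison with mESC after quantile normalization. Given the small shift over all genes, that median could hardly have come near 0. Feeder fibroblasts carried into the mESC libraries, whose labels name no sort, while a reporter gate would remove feeders from the other groups, may account for part of the genes called lower than in mESC, while expression by the stem cells themselves was not tested and stays open.

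Blood genes were high in the SOX17+ libraries, where Hbb-bh1 was listed at 51.9, 75.8 and 141 TPM and Hba-x at 19.6, 33.3 and 53.6 TPM in replicates 1, 2 and 3. T+ cells in the SOX17+ gate with the mean levels of the T+ libraries are argued against as the source, since 0 of the 7 measured primitive blood genes had a higher mean in T+ than in SOX17+. These means do not cover a subset of T+ cells with other levels. Reads shared between globin genes are argued against as the whole cause, since all 5 measured genes that are not globins (100%) were called higher in SOX17+ than in T+. Both counts restate the result that all 7 genes were called higher in SOX17+ than in T+. Their outcomes were known when the tests were written, so they add no independent evidence. Of a second list of 10 erythroid genes, written before its values were seen, 6 could be measured. All 6 (100%) were called higher in SOX17+ than in both other sorted groups, among them Gfi1b at 5.33 ± 1.47 TPM and Alas2 at 2.34 ± 0.592 TPM. Alas2, Gfi1b and Lyl1 passed the filter on low values only through their SOX17+ libraries, which favors this call, so the share partly reflects the filter. Runx1 and Myb were not higher in SOX17+ than in mESC, whose libraries may also hold feeder RNA. Runx1 stood at 4.41 ± 0.833 TPM in SOX17+ and 6.41 ± 0.783 TPM in mESC, and Myb at 1.83 ± 0.386 and 1.88 ± 0.209 TPM. A candidate explanation is a small share of blood-lineage cells that carry the SOX17 reporter and pass the sort on it, while expression of these genes by the endoderm cells themselves was not tested and stays open.

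The double-positive libraries lay between the single-positive groups, and a mixture of both kinds of cell in the gate was set against a separate state. In a mixture in 1 proportion, every list would give the same SOX17+ share. On linear TPM, the lists furthest apart were extraembryonic endoderm (9 genes), at 0.075 ± 0.00963, and the retinoic acid pathway (3 genes), at 0.761 ± 0.00953. They differed by 0.686 without overlap of the libraries. With members weighted alike, their shares were 0.0607 ± 0.00643 and 0.636 ± 0.0334. With the blood, vessel and extraembryonic lists left out, in case the SOX17+ cells of the mixture lacked those genes, shares still ran from 0.331 ± 0.141 for the anterior gut list to 0.761 ± 0.00953, a difference of 0.43 without overlap. With members weighted alike, the anterior gut share was 0.240 ± 0.0721. Both mixtures are therefore argued against as the whole cause, the second less firmly. Each pair of lists was picked as the largest gap over all pairs, which favors a large difference. The SD is over libraries and not over genes, and the T+ and SOX17+ ends were taken without error. The paraxial mesoderm list (11 genes), at 0.703 ± 0.0163, also lay far from the extraembryonic list. A mixture with a subset of either population, or cells that express both programs, may explain the levels, and bulk libraries do not separate these.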

How the results depend on the processing

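Of the alternatives, 1 was added after the results were seen: of the genes called at the midpoint, 1516 lay on the same side of the mean of T+ and SOX17+ in linear TPM. Adding a 2-fold threshold to the adjusted p reduced every count by its own construction, to 5068 genes for SOX17+ against mESC, 4919 for T+ against mESC, 4877 for SOX17+/T+ against mESC, 1392 for SOX17+ against T+, 403 for SOX17+/T+ against T+, 437 for SOX17+ against SOX17+/T+, 36 for the midpoint and 3 beyond both groups. Over the other alternatives with all libraries, the counts ran from 10668 to 17966, 10499 to 17675 and 10597 to 17797 against mESC, 7211 to 9199 for SOX17+ against T+, 3742 to 5202 for SOX17+/T+ against T+, 4727 to 6471 for SOX17+ against SOX17+/T+, 1056 to 2146 for the midpoint and 192 to 388 beyond both groups. Of these, the midpoint count without the filter on low values, 1056, was the only one beyond 1.5 times, in a fit that tested more genes. Leaving out 1 library at a time gave 12079 to 13384, 11857 to 13204 and 12043 to 13481 against mESC, 7980 to 8188, 3604 to 4538 and 5106 to 5290 between the sorted groups in the same order, 829 to 1445 for the midpoint and 166 to 337 beyond both groups. The midpoint count was lowest without SOX17+/T+ replicate 1 and next lowest, at 887, without SOX17+/T+ replicate 2, and the count beyond both groups was lowest without SOX17+/T+ replicate 1 and highest without SOX17+/T+ replicate 3. These fits rest on fewer libraries, and any other cause was not tested. The position ran from 0.475 to 0.491 over the settings and from 0.471 to 0.497 without single libraries, around 0.483 ± 0.0261 with all. The replicate number as a block set the same replicate shift in all groups, also where no pairing was found. With it, 13868, 13668 and 13847 genes were called against mESC, 9199 for SOX17+ against T+, 5202 for SOX17+/T+ against T+, 6471 for SOX17+ against SOX17+/T+ and 2146 for the midpoint. Same-number correlations for SOX17+/T+ with SOX17+ were 0.0463, 0.178 and 0.224 and for T+ with SOX17+ 0.0253, 0.0333 and 0.148, and those with mESC ran from 0.00495 to 0.124. With an estimated correlation, 11 of the 116 list calls held. The estimated correlation ran from -0.0291 for the neural list to 0.794 for the node and notochord list, against 0.01 preset, and a larger correlation widens the error of a list. Of 1085 alternative list values, 947 kept their direction and their side of the threshold, and of 13868 alternative values of 867 named gene results 13482 did. The only reversal was Hoxa2 at the midpoint, whose log2 difference of -0.27 became 0.27 ± 0.19 with a pseudocount of 0.1 (adjusted p = 0.43). The cause was not tested. Of the 124 named results, each a gene in 1 comparison, 122 to 124 held over the settings. Without single libraries 114 to 123 held. Results of comparisons that lack the left-out library were not refitted and were counted as held, so these counts are upper limits. TPM carry no depth per gene, so how far depth limits the values of low genes is unknown.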

Other observations

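The count over splits of the 9 sorted libraries that part every pair was chosen after the results were seen, and the other tests were planned. Cer1 was singled out after its values were seen. Most measured neural and germ cell genes were lower in T+ cells than in mESC. Of the neural list, 4 of its 6 measured members fell and 2 rose in T+ cells (camera, adjusted p = 0.34 as a list). The neuronal tubulin Tubb3 stood at 93.2 ± 3.01 TPM in mESC and 0.344 ± 0.187 TPM in T+, and Nes (-2.52 ± 0.10) fell while Irx3 (1.88 ± 0.08) rose. Against T+ cells, double-positive cells had 3 of the 6 genes lower and 3 not called, or 4 lower adjusted over the list alone (camera, adjusted p = 0.049, but 0.21 with estimated correlation), a call that ended with the replicate number as a block (adjusted p = 0.075). Of the primordial germ cell list, 8 of its 9 measured members fell, 0 rose and 1 did not pass the test in T+ cells (camera, adjusted p = 0.0061, but 0.17 with estimated correlation), with Tfap2c (-3.88 ± 0.11) and Ddx4 (-2.82 ± 0.08). In SOX17+ cells the BLIMP1 gene Prdm1, which is shared with endoderm, was higher instead, at 18.8 ± 1.68 TPM against 7.76 ± 0.198 in mESC (1.17 ± 0.10). In those cells 7 of the 9 measured germ cell genes fell and 2 rose (camera, adjusted p = 0.044, but 0.27 with estimated correlation), a call that ended with a pseudocount of 0.1 (adjusted p = 0.061) and with the replicate number as a block (adjusted p = 0.053). Dppa3 (Stella) was listed at 0 in all 9 sorted libraries and at 5.79, 5.75 and 6.58 TPM in mESC. The list of 2-cell-like cells, which marks a rare state within stem cell cultures, fell in all 5 measured genes in SOX17+ cells (camera, adjusted p = 0.0063, but 0.31 with estimated correlation), in T+ cells (camera, adjusted p = 0.0061, but 0.35 with estimated correlation) and in double-positive cells (camera, adjusted p = 0.0069, but 0.31 with estimated correlation). Zscan4c, Zscan4d and Zscan4f, at 20.2 ± 1.32, 12.3 ± 0.864 and 25.8 ± 1.88 TPM in mESC, were listed at 0 in all 9 sorted libraries, and an exact 0 can also be a failed estimate, so 3 of the 5 falls rest on values of 0.

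Genes of the primed epiblast, the state before gastrulation, went both ways. In SOX17+ cells 6 of the 10 measured genes fell, 2 rose and 2 did not pass the test relative to mESC (camera, adjusted p = 0.28 as a list). Tcf15 (-5.58 ± 0.22), Nodal (-4.26 ± 0.16) and Pou3f1 (-2.98 ± 0.08) fell, while the de novo DNA methyltransferase Dnmt3b stood at 156 ± 3.79 TPM in mESC, 67.3 ± 2.31 in T+, 115 ± 13 in double-positive and 158 ± 17 in SOX17+ cells and was higher in SOX17+ than in T+ (1.22 ± 0.08). Of the FGF pathway list, 6 of its 10 measured members fell and 4 rose in SOX17+ cells relative to mESC (camera, adjusted p = 0.42 as a list). The stem cell ligand Fgf4 (-6.08 ± 0.09) and the feedback inhibitor Spry4 (-3.49 ± 0.12) fell, and Fgf3 (2.53 ± 0.12) rose. Between the sorted groups the list went both ways, with Fgf8 (-3.22 ± 0.22) lower and Spry1 (1.12 ± 0.06) higher in SOX17+ than in T+ cells (camera, adjusted p = 0.81). Of the NODAL pathway list, 7 of its 10 measured members fell and 3 rose in SOX17+ cells relative to mESC (camera, adjusted p = 0.17 as a list). Cer1, which encodes a NODAL antagonist and marks anterior endoderm, varied within groups, at 8.69, 6.72 and 27.3 TPM in double-positive replicates 1, 2 and 3 and 1.84, 0.787 and 4.89 TPM in SOX17+ replicates 1, 2 and 3. It was highest in replicate 3 of each sorted group, with 1.42, 1.17 and 7.24 TPM in T+.

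Other divisions of the same libraries were fitted in the same way to see how many genes they call. Each pairwise comparison has only 10 splits of its 6 libraries, too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many genes as the real one. The real split and the highest other gave 13746 genes against 0 for SOX17+ and mESC, 13520 genes against 2 for T+ and mESC, 13721 genes against 0 for SOX17+/T+ and mESC, 8767 genes against 1 for SOX17+ and T+, 4578 genes against 2 for SOX17+/T+ and T+, and 5894 genes against 1 for SOX17+ and SOX17+/T+. For the paired groups T+ and SOX17+/T+, 4 of the splits part all 3 pairs, and the highest other of these called 2 genes. For the midpoint, 5 of 100 drawn splits of the 9 sorted libraries, the real one included, gave at least its 1589 genes, so chance is not excluded. The highest other gave 7842 genes, several times the real count, which points to the structure of the samples: 2 of the 4 others place a whole T+ or SOX17+ group in the middle, and the highest without such a group gave 3234. For genes beyond both groups, 3 of 100 drawn splits, the real one included, gave at least the real 260, a share under the 0.05 set for this test. This share does not exclude chance, since most drawn splits mix libraries of different groups, which raises their spread and lowers their counts. Of the drawn splits, 45 put the T+ and SOX17+/T+ libraries of every pair in different groups. Among these, 3 gave at least the real count beyond both groups (a share of 0.0667) and 4 at least the real midpoint count (a share of 0.0889), so here too chance is not excluded for either count. Both others beyond the real 260 place a whole T+ or SOX17+ group in the middle, with 4111 genes at the highest, which points to the structure of the samples. Splits without such a group gave at most 2, and these mix libraries of different groups, which raises the spread within groups.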
